A study of Homo sapiens with 2 samples.

How the data were processed

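Poly(A)-selected RNA of LoVo cells was sequenced in 1 library with lentiviral CPEB4 overexpression and 1 GFP control library, per the labels. The deposited table gives FPKM (fragments per kilobase of gene and 1000000 counted fragments) per gene symbol, made by the authors with HISAT2 and featureCounts on hg38, per the submitters' processing notes. The versions, the gene annotation, the strand setting and the handling of fragments that map to several genes are not given in the sources used here. Each column was assigned to its sample by its name, and no column of another sample was present. The table held 41762 rows with a gene symbol each and no repeated symbol. 20676 rows were above 0 in at least 1 library.

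FPKM is a whole number of fragments divided by gene length and library total, so the depth was worked out from the step sizes. The control total was 1.25872 times the overexpression total, a ratio that 935 genes gave to 10 decimal places. The smallest pair of totals that made counts and lengths whole was scaled by the multiple at which the recovered gene lengths most often matched RefSeq (GRCh38.p14) gene spans. This gave 11529435 fragments for CPEB4 overexpression and 14512281 for the GFP control. Each gene's fragments and length were then the smallest whole numbers that gave its values, to a relative tolerance of 1e-09. Where length and both counts share a factor these are lower limits, so the intervals are then too wide and counts of intervals that exclude 1 are lower limits. The annotated exon length (GENCODE 29) was at least 1.5 times the recovered length for 27.2% of 10219 mRNAs with 60 or more recovered fragments. Levels of whole tissue lists are therefore given as summed FPKM, and a gene is said to have under 20 fragments only where its whole RefSeq span would give that. A floor of 3 fragments corresponds to 0.130 FPKM with CPEB4 overexpression and 0.103 FPKM in the control for a 2 kb gene.

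The ratio of a gene was log2((FPKM overexpression + 1)/(FPKM control + 1)), which understates the difference of low genes. Genes at 1 FPKM or more in at least 1 library were kept (12439). Genes were counted at 2-fold for all genes and 1.5-fold for list members. Folds in the text are ratios of FPKM without pseudocount, with 95% Clopper-Pearson intervals from the recovered fragments. A fold against 0 is a lower bound against the floor of 3 fragments. Counting intervals do not cover the variation between cultures. Because FPKM is not a count and each group had 1 library, no test across genes was run.

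The 44 gene lists, the named-gene rule, the groups, the main settings and 10 of the alternatives run were fixed before the data were examined. A list's median log2 ratio was placed among those of 10000 random lists of the same size, drawn from the same 20 expression bins, as a description of these libraries. Lists with under 5 measured members were left out of the tally of lists. Symbols were matched to older names through RefSeq. Named were CPEB1 to CPEB4, the 12 highest and 12 lowest ratios among genes at 5 FPKM or more in a library, and up to 3 members at each end of each list described, or any member of a list of 11 genes or fewer. ATF4, ATP4A, ATP4B, MLXIPL and PER2 were named after their values were seen. Some genes that the rule names are not reported here. 5 further lists were written after the largest differences were seen: stomach gland and pit genes, plasma cell genes, stroma and tumour tissue genes, glucose and fasting responsive genes, and tubulin and actin cytoskeleton genes.

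Gene positions, GC content and 3' UTRs came from GENCODE 29 on GRCh38, the build that hg38 names. The trend of the ratio with recovered length and GC content was removed with a polynomial of degree 3 in each, over the 11711 kept genes (94.1%) with a GC value, and once more with annotated exon lengths. The cytoplasmic polyadenylation element was searched in the 3' UTRs of 10502 mRNAs, and 303 mRNAs without a usable 3' UTR counted as not searched.

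The steps were tested on simulated libraries of these depths with 200 genes changed among 12259 genes past the filter. The changed genes were drawn only from those at 5 FPKM or more in a deposited library. They also had at least 50 expected fragments at the depth of the overexpression library. The shares called below therefore need not hold for lower genes. Of 50 genes raised 2.5-fold, 44 were called at the 2-fold limit, and of 50 raised 4-fold, 50. Of 50 genes lowered 2.5-fold, 48 were called, and of 50 lowered 4-fold, 50. Of 100 lists of unchanged genes, 1 lay outside the middle 95% of random lists. Those lists were drawn at random from genes with counting noise only, so they do not test lists whose genes move together. Fragments were recovered exactly for 86.1% of rows above 0 and up to a whole factor for 100% of them. The simulation started from the recovered lengths and fragments and was given the totals. It therefore did not test the choice of the multiple, and the 86.1% need not hold for the deposited values. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.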

Results

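RNA from LoVo cells, an established human colorectal cancer cell line, was measured by poly(A)-selected RNA sequencing in 2 libraries. In 1 library the cells carried a lentiviral vector for CPEB4, and in the other, the control, they expressed GFP. CPEB4 is a cytoplasmic polyadenylation element binding protein, which binds U-rich elements in 3' UTRs and regulates poly(A) tail length and translation. The samples' own titles spell the gene CEBP4, while the series describes CPEB4. The comparison asked how the transcriptome of LoVo cells differed when CPEB4 was overexpressed. The values were FPKM per gene symbol for 41762 genes, and their step sizes gave totals of 11529435 counted fragments for CPEB4 overexpression and 14512281 for the GFP control. There was 1 library per group, so no difference below has a replicate check and no p-value is given. Intervals after a fold are 95% exact binomial (Clopper-Pearson) intervals and cover counting error only.

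CPEB4 was higher in the library labelled as its overexpression, at 1.70 FPKM against 0.346 FPKM in the control, a 4.91-fold difference (interval 3.43 to 7.17) that rested on 152 and 39 fragments. The gene lies on chromosome 5 from 173888280 to 173961976, plus strand (GRCh38, GENCODE 29), and its counted length was 7769 nt. The sources used here do not say which part of the transcript the vector carried or whether vector transcripts were counted, so these values do not separate them from the cells' own transcript. CPEB4 ranked 9656 of 10805 mRNA rows by FPKM in its own overexpression library and 61 by log2 ratio. CPEB3, a close paralog, stood at 0.746 against 0.430 FPKM (1.73-fold, interval 1.11 to 2.73). CPEB2 was at 0.921 against 0.691 FPKM, with an interval that included 1, and CPEB1 at 2.16 against 2.36 FPKM.

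Most genes had similar levels in the libraries. Of 12439 genes at 1 FPKM or more in at least 1 library, 11293 (90.8%) lay within 1.5-fold on the log2(FPKM + 1) scale, and Pearson's r of those log2 values was 0.978 across genes, which are not independent replicates. On that scale, 169 genes were at least 2-fold higher with CPEB4 overexpression and 214 at least 2-fold lower. The counting interval excluded 1 for 73 and 55 of them. At any fold, it excluded 1 for 6105 of the 12439 genes. The median log2 ratio of all these genes was 0.13. Short RNAs with few fragments made up much of both counts. Of the 25 miRNA rows called higher and the 47 called lower, 71 had under 20 fragments even with the gene's whole RefSeq span as the counted length. Among mRNA rows, 61 were higher and 52 lower, and the same held for 10 of these calls. The span can exceed the counted length, so 10 is a lower limit. By recovered fragments, 19 of these calls had under 20. In simulated libraries of these depths with counting noise only, 194 of 12059 unchanged genes past the filter passed the 2-fold limit, 5 of them with 20 simulated fragments or more. The simulation started from the recovered fragments, which are lower limits for some genes.

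Among the 12 genes with the highest ratio, COL3A1, a fibrillar collagen of fibroblasts, stood at 5.62 against 0.326 FPKM (17.2-fold, interval 9.82 to 33.0). TXNIP, an inhibitor of glucose uptake and thioredoxin that is induced by glucose, was at 79.0 against 18.6 FPKM (4.25-fold, interval 3.92 to 4.60). TSC22D3, the glucocorticoid-induced leucine zipper gene, was at 40.2 against 9.66 FPKM (4.16-fold, interval 3.67 to 4.74). PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was at 42.7 against 11.5 FPKM, NUPR1 at 25.1 against 6.80 FPKM and CHAC1, which degrades glutathione, at 38.5 against 10.8 FPKM. GTPBP6, at 7.20 against 1.40 FPKM, is uncertain because it has more than one annotated copy. LOC102723454, a noncoding RNA, was at 10.2 FPKM against 0, with 2 recovered fragments, a lower limit, and an interval that included 1. The other 4, MIR4734, MIR6732, SNORD88C and MIR4479, each had under 20 fragments.

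The 12 genes with the lowest ratio were led by digestive enzymes of the stomach. Pepsinogen PGA3 was at 171 FPKM in the control and listed at 0 with CPEB4 overexpression, at least 229.6-fold lower against a floor of 3 fragments. Progastricsin PGC was at 148 FPKM against 0 (at least 71.0-fold), gastric lipase LIPF at 61.4 FPKM against 0 (at least 359.9-fold) and PGA5 at 26.2 FPKM against 0 (at least 46.9-fold). PGA3 and PGA5 are near-identical copies, so the split of fragments between them is uncertain. GKN1, a secreted protein of gastric surface cells, stood at 18.3 FPKM in the control against 0.740. IGHA1, the heavy chain constant region of immunoglobulin A, stood at 28.3 against 0.654 FPKM. HSPA1A, an inducible HSP70, was at 97.4 FPKM in the control against 13.1 with CPEB4 overexpression, 7.45-fold lower (interval 6.69 to 8.32). IGLC2, a constant region of the immunoglobulin light chain, was at 6.46 FPKM against 0, with 3 recovered fragments, a lower limit, and an interval that included 1. MIR7113, MIR4320, SNORD34 and SNORA1 each had under 20 fragments. RNA or reads of stomach tissue in the control library are a candidate source of the stomach and immunoglobulin transcripts, as described below. The differences of those genes therefore need not be an effect of CPEB4.

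**Figure D1:**
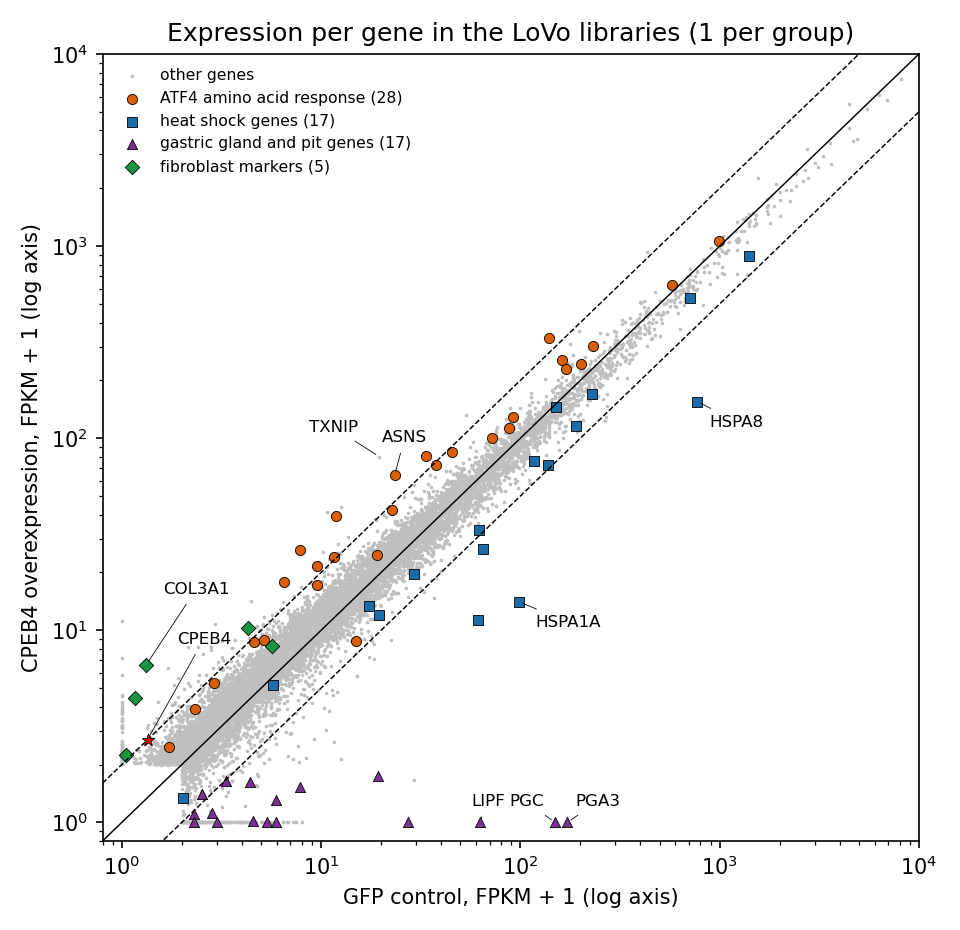
FPKM + 1 of each of 12439 genes in the GFP control (x, log axis) and with CPEB4 overexpression (y, log axis), 1 library per group; each point is a gene, colours mark 4 gene lists with the number of members measured, the red star is CPEB4, the solid line marks equal values and the dashed lines a 2-fold difference. Most genes lie between the dashed lines, while HSPA8 and HSPA1A lie below them, PGA3, PGC and LIPF sit at 0 with CPEB4 overexpression, and TXNIP, ASNS and COL3A1 lie above.

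Genes of the amino acid response, which the transcription factor ATF4 induces when amino acids are short, were higher with CPEB4 overexpression. Of 28 measured members, 17 were at least 1.5-fold higher and 1 at least 1.5-fold lower on the log2(FPKM + 1) scale used for all list counts, and the counting interval lay above 1 for 27. The list's median log2 ratio was 0.81, above all 10000 random lists matched on size and expression, 95% of which lay between -0.11 and 0.14. NUPR1, a stress-induced chromatin protein, was 3.69-fold higher (interval 2.02 to 7.14) and CHAC1 3.56-fold (interval 3.07 to 4.13). Asparagine synthetase ASNS, on chromosome 7 from 97852118 to 97872542, was at 63.2 against 22.4 FPKM (2.82-fold, interval 2.59 to 3.08). ATF4 itself was at 243 against 201 FPKM (1.21-fold, interval 1.16 to 1.25). The amino acid transporter SLC7A5 was at 1065 against 997 FPKM and its partner SLC3A2 at 629 against 574 FPKM. ATF5 was the exception, at 7.78 against 13.96 FPKM. Collagen-rich fibroblast markers were also more abundant in this library, at a summed 28.4 FPKM against 9.29 FPKM in the control.

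Heat shock genes were lower with CPEB4 overexpression. Of 17 measured members, 11 were at least 1.5-fold lower, 4 of them at least 2-fold, and none was 1.5-fold higher. The counting interval lay below 1 for 15. The median log2 ratio was -0.66, below all 10000 matched random lists, 95% of which lay between -0.18 and 0.13. HSPA8, the constitutive HSC70 on chromosome 11 from 123057489 to 123063230, was at 772 FPKM in the control against 154 (5.01-fold lower, interval 4.85 to 5.17). HSPA1B was at 60.2 against 10.3 FPKM (5.86-fold lower, interval 5.19 to 6.63), though it and HSPA1A are near-identical, so their individual values are uncertain. The mitochondrial chaperonin HSPD1 was at 150 FPKM in the control against 144, with an interval that included 1, and HSPA4L at 4.70 against 4.20 FPKM. Stomach gland and pit genes summed to 467 FPKM in the same control library, against 4.46 FPKM with CPEB4 overexpression.

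Several metabolic and proliferative groups lay above their matched random lists by smaller amounts. Hypoxia and glycolysis genes had a median log2 ratio of 0.27 (percentile 99.98), with 9 of 34 members at least 1.5-fold higher and none lower. They were led by MXI1, a MYC antagonist (9.35 against 3.71 FPKM, 2.52-fold), the mitophagy receptor BNIP3L (2.27-fold) and the aldolase ALDOC (2.16-fold), while ANKRD37 was at 6.42 against 9.38 FPKM. Fatty acid synthesis and storage genes had a median of 0.26 (percentile 99.6), with 3 of 29 members at least 1.5-fold higher: PDK4, which inhibits pyruvate dehydrogenase (6.28 against 2.18 FPKM), the stearoyl-CoA desaturase SCD (308 against 176 FPKM) and the desaturase FADS1 (62.0 against 36.2 FPKM). PLIN3 was at 205 against 304 FPKM. DNA replication genes had a median of 0.22 (percentile 99.9), with 2 of 36 members at least 1.5-fold higher, among them the helicase subunit MCM6 (1.62-fold), and none lower. Genes of G2 and mitosis did not stand apart (median 0.06, percentile 45.97), but their percentile became 0.14 with a trend in gene length and GC content removed. Translation initiation factors had a median of 0.14 (percentile 99.5), and none of the 33 reached 1.5-fold. That list lay inside the range of random lists (percentile 75.5) with that trend removed. Between the same libraries, fibroblast markers summed to 28.4 against 9.29 FPKM and stomach genes to 4.46 against 467 FPKM in the control.

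NF-kB target and chemokine genes had a median log2 ratio of -0.16 (percentile 0.19). Of 18 measured members, 3 were at least 1.5-fold lower and none higher. The cytokine IL6 was at 1.90 against 4.15 FPKM in the control (2.18-fold lower, interval 1.43 to 3.40) and TRAF1 at 0.370 against 1.32 FPKM, while the inhibitor of apoptosis BIRC3 was at 2.72 against 1.64 FPKM. The 6 measured metallothionein list members had a median of -0.26 (percentile 0.73). MT1G was at 3.13 FPKM in the control against 0.219, and MT2A at 398 against 331 FPKM, and the list's percentile became 13.4 without the trend with length and GC content. The control also held stomach genes at a summed 467 FPKM against 4.46 and plasma cell genes at 63.3 FPKM against 3.52. Whether the source of those transcripts also gave part of the NF-kB or metallothionein differences was not tested. In total, 9 of the 38 lists with at least 5 measured members lay outside the middle 95% of their matched random lists. With independent genes and lists, 1.9 would. Genes of a list can move together and some lists share genes, so these numbers do not measure an excess over chance.

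**Figure D2:**
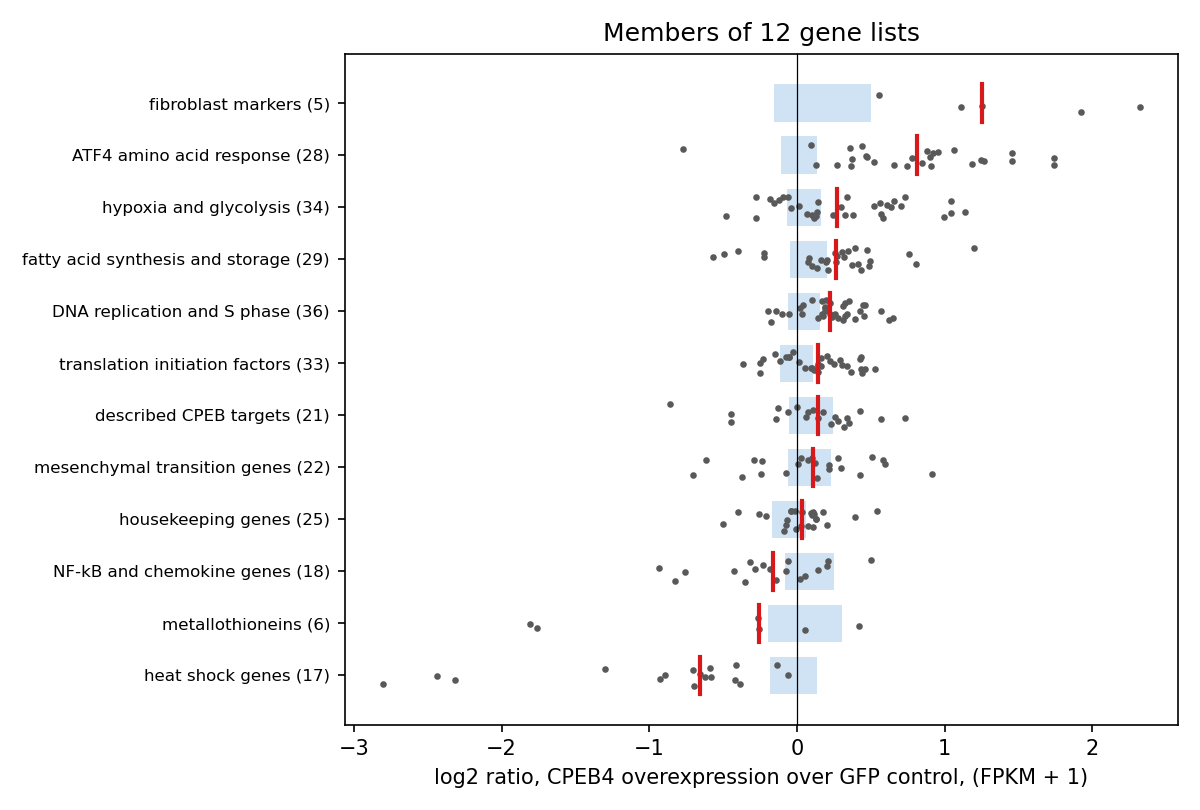
Log2 ratio of FPKM + 1, CPEB4 overexpression over GFP control (x), of each measured member (dots, scattered vertically for legibility) of 12 gene lists (y, number of members measured in brackets); red bars are list medians and blue bands hold 95% of the medians of 10000 random lists matched on size and expression. The medians of the ATF4 list (0.81) and the heat shock list (-0.66) lie outside their bands, and those of described CPEB targets (0.14) and mesenchymal transition genes (0.11) lie inside.

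Genes described as targets of CPEB proteins did not stand apart from matched random lists (median log2 ratio 0.14, percentile 70.3). Of 21 measured members, 1 was at least 1.5-fold higher, ZFP36, which destabilises AU-rich mRNAs (12.3 against 7.001 FPKM), and 1 lower, the AP-1 subunit JUN (13.99 against 26.2 FPKM). VEGFA was at 18.9 against 12.4 FPKM (1.52-fold, interval 1.37 to 1.69) and HIF1A at 11.4 against 8.27 FPKM. The polyadenylation and deadenylation machinery had a median of 0.23 (percentile 97.2), and on the log2(FPKM + 1) scale its highest members were BTG1 (1.64-fold), CNOT10 (1.55-fold) and the poly(A)-binding protein PABPC1 (353 against 250.3 FPKM).

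Several lists of invasion, signalling and differentiation genes lay inside the range of their matched random lists. Mesenchymal transition genes had a median of 0.11 (percentile 60.4): SNAI2, a repressor of E-cadherin, was at 2.79 against 1.01 FPKM and TGFBR2 at 8.24 against 5.11 FPKM, while fibronectin FN1 was at 1.63 against 3.27 FPKM. Matrix protease and invasion genes had a median of 0.08 (percentile 61.7) and epithelial junction and keratin genes 0.08 (percentile 64.0), with CLDN4 at 40.7 against 68.1 FPKM. Wnt target genes had a median of 0.15 (percentile 62.1), with AXIN2 at 1.99 against 1.04 FPKM. Angiogenic factors had a median of 0.23 (percentile 86.3), apoptosis regulators 0.13 (percentile 53.1), YAP targets 0.16 (percentile 79.9) and growth factor receptors and ligands 0.20 (percentile 88.6), where the counting interval lay above 1 for 10 of 19 members and below 1 for none. Over all 12439 kept genes the interval excluded 1 for 6105, and the median log2 ratio of those was 0.28. Notch and secretory fate genes had a median of 0.19 (percentile 64.3, 13 measured), with OLFM4 at 2.73 FPKM against 0, NOTCH3 at 4.99 against 3.16 FPKM and DLL3 at 2.73 against 4.74 FPKM. With the trend in length and GC content removed, that list's median was 0.36 (percentile 99.5), above its random range, but it was 0.29 and inside that range (percentile 96.3) with annotated exon lengths in place of recovered lengths. Immediate early genes went both ways, with KLF10 at 19.2 against 9.35 FPKM and FOSL1 at 19.3 against 39.1 FPKM. So did interferon-stimulated genes, where IRF7 was at 18.1 against 9.34 FPKM and OASL at 1.71 against 8.20 FPKM.

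The unfolded protein response list, of the endoplasmic reticulum, had a median of -0.06 (percentile 9.52) and also went both ways. DDIT3, the transcription factor CHOP, was at 13.3 against 3.45 FPKM (3.84-fold, interval 2.85 to 5.24) and ATF3 at 20.3 against 11.9 FPKM. The luminal chaperone cofactor SDF2L1 was at 85.9 against 155 FPKM and MANF at 51.8 against 83.1 FPKM. The list's percentile became 0.14 without the trend with length and GC content.

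Among differentiation genes, intestinal alkaline phosphatase ALPI, on chromosome 2 from 232456123 to 232460032, was at 931 against 430.0 FPKM (2.17-fold, interval 2.12 to 2.21). The enterocyte list it belongs to had a median of 0.18 (percentile 79.3, 10 measured). In the goblet and mucin list, 3 of 14 members were at least 1.5-fold higher and 5 lower. Its median was 0.12 (percentile 40.5) while its mean was -0.34. REG1A was at 7.19 against 1.79 FPKM, and TFF1, MUC5AC and MUC6, all also made by the stomach, were at 6.86, 4.92 and 3.54 FPKM in the control against 0.529, 0.305 and 0.0108. In the list of fibroblast markers, 4 of 5 measured members were at least 1.5-fold higher, with a median of 1.25, above all matched random lists. That median was 0.63 without the filter on low values, 0.70 with a pseudocount of 5 FPKM and 3.22 with 0.1 FPKM. The filter favoured this direction, since COL3A1, COL1A2 and COL6A3 passed it only through the CPEB4 overexpression library. Of all 11 genes of the list, 8 were higher with CPEB4 overexpression and 1, POSTN, was lower (0 against 0.387 FPKM). PDGFRA and FAP were at 0 in both libraries. COL1A2 was at 3.41 against 0.166 FPKM (20.6-fold, interval 11.8 to 39.4), COL1A1 at 9.23 against 3.29 FPKM and COL6A3 at 1.25 against 0.0456 FPKM. The collagens were higher in the library in which the stomach transcripts were lower, at a summed 4.46 FPKM with CPEB4 overexpression and 467 FPKM in the control.

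Of the leukocyte, neuronal and liver lists only CD68 (10.8 against 9.95 FPKM), TUBB3 (99.2 against 163 FPKM) and CPS1 (55.9 against 28.4 FPKM) reached 1 FPKM, and of the endothelial list EGFL7, VWF and ESAM did. Housekeeping genes had a median of 0.04 (percentile 93.4), and none of 25 differed by 1.5-fold. Cytosolic ribosomal protein genes had a median of -0.13 (percentile 24.2) and the 13 mitochondrially encoded mRNAs -0.22 (percentile 7.52), and none of either list differed by 1.5-fold. Among abundant noncoding RNAs, RN7SL1, of the signal recognition particle, was at 127 against 269 FPKM, and SNHG1 was at 37.9 against 20.3 FPKM.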

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

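Tests chosen after the data were seen were those on mRNA rows, on genes with 20 recovered fragments, with the trend in length and GC content removed, and without stomach, plasma cell and stroma genes. No alternative turned the direction of CPEB4 or of any list outside its random range. The 169 higher and 214 lower genes became 388 and 298 with a pseudocount of 0.1 FPKM (the latter within 1.5 times) and 16 and 28 with 5 FPKM. They were 58 and 53 at 5 FPKM or more in a library, 378 and 373 after rescaling to a total of 1000000, and 386 and 388 without mitochondrial genes. They were 730 and 416 at 1.5-fold, 11 and 39 at 4-fold, and 73 and 55 where the counting interval excluded 1. They were 61 and 52 among mRNA rows, 65 and 45 with at least 20 recovered fragments, 152 and 141 with the trend removed, and 157 and 133 with that trend on annotated exon lengths. Rescaling raises all values against the fixed pseudocount and filter, and the other limits keep fewer or more genes by construction. The log2 ratio of CPEB4, main value 1.003, was 2.01 and 0.33 with pseudocounts of 0.1 and 5 FPKM and 1.41 and 1.43 after both rescalings, since its level lies near the pseudocount. The scaling factors themselves were at most 0.07 on the log2 scale.

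Of 339 values of the 38 list medians under alternatives, 319 stayed inside the median's 95% interval or, for the 5 fibroblast markers, which have none, their members' range. After rescaling, the ATF4 list had 0.95, G2 and mitosis 0.13, antigen presentation 0.16, cytosolic ribosomal proteins -0.0613 and the polyadenylation machinery 0.32. Without mitochondrial genes, the values for G2 and mitosis, ribosomal proteins and the polyadenylation machinery were 0.13, -0.0683 and 0.31. With the median ratio set to 0, DNA replication had 0.16, ribosomal proteins -0.20 and the nuclear-encoded respiratory chain -0.17. With the trend removed, G2 and mitosis had -0.0391, antigen presentation 0.16, ribosomal proteins -0.0163 and the respiratory chain 0.0275. On annotated exon lengths the last 3 had 0.18, -0.0206 and 0.0157. Fibroblast markers, main value 1.25, had 3.22 with a pseudocount of 0.1 FPKM, 0.70 with 5 FPKM and 0.63 without a filter. The polyadenylation machinery had 0.14 with 5 FPKM. The cause of these shifts was not tested. Of 214 values for the 24 named genes, 195 stayed inside the counting interval put on the log2(FPKM + 1) scale, or past the floor of 3 fragments for genes at 0, and none changed sign. Summing rows of the same symbol moved nothing, since no symbol was repeated. No paired analysis was possible because each group had 1 library. Depth limits short and low genes: 4 of the 12 highest and 4 of the 12 lowest named genes had under 20 fragments even at their whole RefSeq span.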

Other observations

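The tests of stomach and immunoglobulin transcripts and of culture differences, the other matchings of 3' UTRs and the 5 added gene lists were chosen after the results were seen. Genes that respond to glucose or fasting were higher with CPEB4 overexpression: 11 of 17 measured members of a list written after TXNIP and ARRDC4 were seen were at least 1.5-fold higher and none lower. The median log2 ratio was 0.79, above all 10000 matched random lists. Beside TXNIP and TSC22D3, the arrestin ARRDC4 stood at 4.86 against 1.44 FPKM (3.38-fold, interval 2.62 to 4.38), MLXIPL, a glucose-sensing transcription factor, at 4.10 against 1.20 FPKM and the clock gene PER2 at 1.56 against 0.402 FPKM. FOXO1 was at 1.496 against 1.34 FPKM, with an interval that included 1. Because the list was chosen on these values, it is not independent evidence of a direction.

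Tubulin and actin cytoskeleton genes were lower with CPEB4 overexpression. Of 27 measured members, 7 were at least 1.5-fold lower and none higher, the counting interval lay below 1 for 23, and the median was -0.37, below all matched random lists. TUBB4B was at 705 against 1371 FPKM in the control (1.94-fold lower, interval 1.90 to 1.98), TUBA1C at 714 against 1223 FPKM and the actin bundler FSCN1 at 369 against 632 FPKM. TPM3 was at 69.7 against 64.7 FPKM. This list too was written after tubulin values were seen, and tubulin genes have near-identical copies. Across 10297 mRNAs with 60 or more recovered fragments, the median log2 ratio went from -0.05 in the shortest of 8 classes of recovered length to 0.25 in the longest (Spearman's rho 0.300 across genes, which are not independent replicates). The list's median was -0.21 with that trend removed, and -0.27 with annotated exon lengths in place of recovered ones, both below all matched random lists.

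The GFP control held transcripts of several stomach cell types. Of 26 stomach genes, 4 of them also on the goblet and mucin list, 17 reached 1 FPKM in the control. With CPEB4 overexpression, 0 of the 26 reached 1 FPKM, and 13 were listed at 0 FPKM. Of the 20 that were not among the genes with the largest differences, 11 were at 1 FPKM or more in the control. The stomach genes included chief cell (PGA3, 171 FPKM), parietal cell (ATP4A, 4.34 FPKM, and ATP4B, 4.92 FPKM) and surface cell genes (GKN1, 18.3 FPKM), and the list summed to 467 FPKM against 4.46 FPKM. Plasma cell genes summed to 63.3 against 3.52 FPKM, 17.96 times higher in the control, which does not show which cells made them, so expression by the LoVo cells stays open. RNA or reads from stomach tissue in the control library remain a candidate source, and whether they entered at the bench, the sequencer or the processing stays open.

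Leaving out the stomach, plasma cell and stroma lists gave 162 higher and 189 lower genes. In the stroma list, 8 of 10 measured genes were at least 1.5-fold higher with CPEB4 overexpression (OLFM4, 2.73 FPKM against 0). Its FPKM summed to 137 against 122 in the control, while its share of fragments estimated from annotated exon lengths was 987 against 989 per 1000000, with COL5A1, the most abundant, at 94.6 against 111 FPKM. Of all 20 genes of the list, 16 were higher with CPEB4 overexpression and 2 in the control. At 1 FPKM or more were 10 with CPEB4 overexpression and 5 in the control, so the filter favoured the former. Whether the LoVo cells or RNA of other tissue gave these transcripts was not tested.

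The amino acid response list was higher with CPEB4 overexpression. A trend with length and GC content is argued against as its cause, since the median was 0.75 with the trend removed and 0.77 with the trend on annotated exon lengths, each above all matched random lists. Counting error is argued against by 27 members with an interval above 1. A difference in culture or harvest, such as medium use, could give the same pattern and cannot be told apart from an effect of CPEB4, because there was 1 library per group. Both stay open.

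The heat shock list was lower with CPEB4 overexpression. Its median was -0.60 with the trend removed and -0.58 with the trend on annotated exon lengths, each below all matched random lists, and 15 members had an interval below 1, so neither the trend nor counting error accounts for it alone. A difference in temperature, handling or harvest between the cultures could do so and cannot be told apart from an effect of CPEB4 with 1 library per group.

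A hypothesis was that mRNAs with a cytoplasmic polyadenylation element in the 3' UTR would shift. With an element anywhere in the 3' UTR, the median log2 ratio exceeded that of mRNAs without one by 0.139, against 0.119 to 0.138 for 95% of random assignments matched on 3' UTR length, AU content and expression. That matching used 10 classes of length, 10 of AU content and 4 of expression. With 20, 20 and 2 classes the difference was 0.127, inside 0.104 to 0.128, and with 20, 20 and 4 it was 0.107, inside 0.0796 to 0.108. With an element in the last 150 nt the differences under these matchings were 0.0615, inside 0.0404 to 0.0657, then 0.0587, above 0.0337 to 0.0584, and 0.0478, inside 0.0249 to 0.0494. The excess over the median random assignment was 0.01 in each. The planned test used an element anywhere in the 3' UTR with 10, 10 and 4 classes, and its difference lay outside its range. In the last 150 nt, the difference with those classes lay inside. In all, 4 of the 6 comparisons lay inside their ranges. Whether such mRNAs shifted stays open.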
